A study of Homo sapiens and Pan troglodytes with 4 samples.

How the data were processed

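The samples were mature sperm from 2 human and 2 chimpanzee donors. Per the labels, genomic DNA was bisulfite treated and made into Illumina genomic libraries with paired-end adaptors, and the individuals were sequenced separately. The authors deposited the processed data as 1 list of hypomethylated regions per species, in BED layout without a header. The deposited lists hold, for each region, a start, an end and a fraction, which was read here as the methylation level of the region from its range alone, since no header or label names the column. The aligner, the region caller, its thresholds, the read depth and how the 2 donors of a species were combined are not given in the sources used here. Per the submitters' processing notes the build was hg18, which the labels give for the chimpanzee samples as well. The names of the deposited lists give hg18 for human and panTro2 for chimpanzee, and the chimpanzee chromosomes 2a and 2b fit panTro2, so those builds are used for the coordinates.

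The human list held 79169 and the chimpanzee list 70032 regions, of which 758 and 399 on Y were left out. No regions overlapped within a list. The samples were grouped by species, and each species counted as 1 list, so species were compared by description only, with the ratio over all chromosomes, the number of homologous chromosomes going the same way and the range when each chromosome was left out. Depth per region is unknown, so a region's level has no interval. A bisulfite level also depends on conversion, mapping in repeats and the caller's smoothing, none of which could be examined from the lists. A greater depth in one species would let more short or partly methylated regions be called there, which would change numbers, widths and the share paired.

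A chromosome's span ran from its first to its last HMR less gaps over 1 Mb without any HMR, and density was regions per Mb of that span. The correlation of chromosome values between the species used 100000 permutations, two-sided, with Benjamini-Hochberg adjustment over 3 relations. Clustering was compared with 1000 random placements of the same regions on the same chromosomes. Windows were 1 Mb, and a region belonged to the window of its midpoint.

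No alignment between the builds was used and no coordinates were converted. HMRs of homologous chromosomes were paired by order and spacing only, with a dynamic programming search for chains in which successive pairs have similar distances in both species, in either orientation. The spacing tolerance was 150 bp plus 0.6% of the distance, each HMR passed over cost 0.8 score units, up to 6 HMRs back were searched, the longest step was 2 Mb and a chain had at least 6 pairs. A chain was kept when its score was above 34.5, the best found in 48 searches between non-homologous chromosomes. These settings were chosen by trial on chromosomes 17, 19, 20, 21 and X, after the lists had been examined, to give the most pairs above the non-homologous score, so the shares paired are not independent of that choice. A control with reversed spacing had been planned, but the reversed orientation was searched as a real inversion and the control was run between non-homologous chromosomes alone. A second set of 48 non-homologous searches, not used for the threshold, gave 51 pairs, all from 1 search. Overlap was judged after the offset of a neighbouring pair, up to 2 on each side, was removed. Intervals of shares are Wilson 95% intervals and cover counting error only.

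The matching was tested on simulated data made from human chromosomes 21, 17 and X, with 30% of the regions dropped and 15% added, on 1121 to 5256 regions. Between 97.8% and 99.9% of the true partners were found, and between 97.1% and 99.0% of the pairs were correct. The simulated changes of spacing were close in scale to the matching tolerance, and added regions were placed uniformly at random. No rearrangement inside a chromosome was simulated, the true orientation was scored, and these chromosomes were also used to choose the settings. Those shares therefore do not give the accuracy in the real lists. The clustering test gave p under 0.05 for 1 of 40 random maps.

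The regions named in the text were chosen by a rule set before the data were examined. It took the 5 longest HMRs of each list, the 5 densest 1 Mb windows, the 5 longest HMRs inside a chain without a partner, and the 5 pairs with the greatest width ratio in each direction among pairs with both widths of at least 500 bp. The stretch of X between 2 chains, the stretches of highly covered windows and the narrow peak of widths were chosen after the data had been seen.

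Alternatives set before the data were examined were a list restricted to the upper 75% of the fraction, merging of HMRs under 500 bp apart, autosomes only, HMRs of at least 1 kb only, spans with no gap removed, a halved or doubled spacing tolerance, and a partner overlapping by at least 50% of the shorter region. Because a low fraction is the stronger hypomethylation, the upper 75% drops the least methylated regions. Lists without the 25% of HMRs highest in the fraction, merging under 2 kb and pairing by any overlap were added after the data had been seen. Both filters on the fraction were cut at each list's own quartile, so the level of the cut differed between the species. A planned count of gene promoters and gene lists inside HMRs was not run, because the gene table at hand is of another build than the lists. Tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.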

Results

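Mature sperm DNA from 2 human and 2 chimpanzee donors was measured by whole-genome bisulfite sequencing, and 1 list of hypomethylated regions (HMRs) per species was analysed. An HMR is a stretch of DNA whose CpG sites carry little methylation in a genome that is otherwise highly methylated in sperm. Human regions had coordinates on hg18 and chimpanzee regions on panTro2. After regions on Y were left out, 78411 human and 69633 chimpanzee HMRs on the 22 autosomes and X remained, with chimpanzee 2a and 2b joined as the counterpart of human chromosome 2. Each region carried a fraction between 0 and 0.423, read here as its methylation level, although no header states this. The lists name no donor, so there was no replicate error, and no p-value between the species was computed. The number of reads behind each region is unknown.

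Human sperm had more HMRs than chimpanzee sperm, and they covered more of the genome, while the typical width was nearly the same. Human HMRs covered 139.6 Mb, or 4.91% of the chromosome spans, and chimpanzee HMRs covered 125.1 Mb, or 4.38%. The number of regions was 1.13 times higher in human sperm, with a ratio above 1 on 23 of 23 chromosomes. It ranged from 1.02 on chromosome 19 to 1.24 on chromosome 21 among autosomes and was 1.56 on X. Covered length was 1.12 times higher in human sperm and was higher on 19 of 23 chromosomes, from 0.959 on chromosome 2 to 1.25 on chromosome 21 among autosomes, with 2.47 on X. Chromosome X held much of that excess, since the ratio of covered length was 1.06 without it and between 1.11 and 1.13 when any single autosome was left out.

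The median width was 1244 bp in human sperm (quartiles 674 and 2302 bp) and 1252 bp in chimpanzee sperm (quartiles 699 and 2324 bp). Their ratio was 0.994 over all chromosomes and 0.974 without X, and the human median was the larger on 8 of 23 chromosomes. Regions under 500 bp made up 16.7% of human and 15.8% of chimpanzee HMRs. Regions over 5 kb were about as many in both lists, 3321 and 3275, but this joined opposite differences. On autosomes there were 2701 human and 3170 chimpanzee regions over 5 kb, a ratio of 0.852, and on X there were 620 and 105. Above 10 kb there were 587 human and 323 chimpanzee regions, a ratio of 1.82, with 438 and 314 on autosomes (1.39) and 149 and 9 on X. The order of the median widths turned when HMRs under 500 bp apart were merged or when only HMRs of at least 1 kb were kept, to a ratio of 1.01 in both cases.

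**Figure D1:**
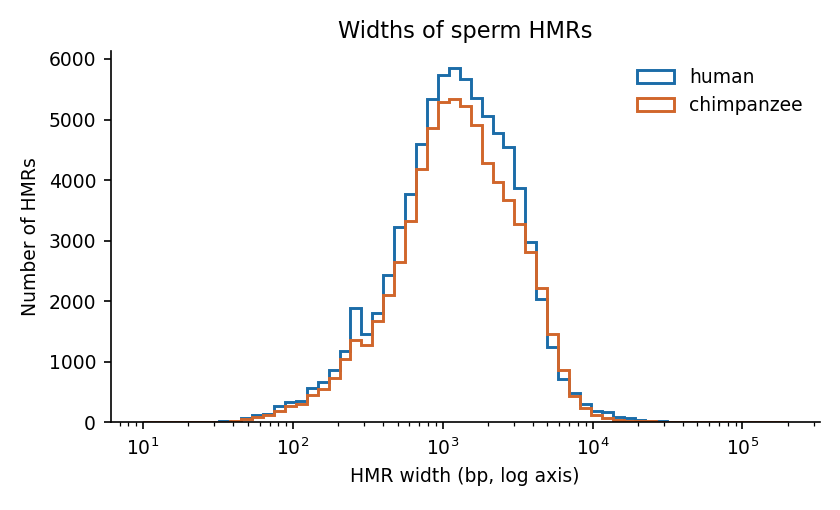
Number of HMRs (vertical axis) by width in bp (horizontal log axis) in human and chimpanzee sperm, drawn as step outlines. Both distributions peak near their medians of 1244 and 1252 bp, and a narrow extra peak stands near 270 bp in both.

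Over all chromosomes, wider HMRs carried lower levels in both species. Human X was an exception at the wide end, with a median level of 0.184 in regions of 4 kb or more and 0.164 over all its HMRs. In the whole lists the median level was 0.193 in human and 0.162 in chimpanzee regions narrower than 250 bp. In regions of 4 kb or more it was 0.0430 and 0.0246. Across regions within each list, Spearman's rho between width and level was -0.45 in human and -0.50 in chimpanzee sperm, and regions are not independent replicates. The median level over all HMRs was 0.118 in human and 0.0779 in chimpanzee sperm. The authors' scaling and depth are not given in the sources used here, so the levels of the lists were set side by side without a test.

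Chromosome X was rich in HMRs in human sperm and at the low end of the chromosomes in chimpanzee sperm. In human sperm HMRs covered 8.83% of the span of X against an autosomal median of 4.57%, and only chromosome 19 was higher, at 11.5%. In chimpanzee sperm X was poorer in HMR sequence than each of the 22 autosomes, with 3.49% covered against an autosomal median of 4.35%. Human X held 35.3 HMRs per Mb with a median width of 1608 bp, against autosomal medians of 27.0 per Mb and 1226 bp. Chimpanzee X held 22.2 per Mb with a median width of 1143 bp, against 24.5 per Mb and 1253 bp, with 4 autosomes lower in density and 2 lower in width. The chimpanzee ratios of X to the autosomal median were 0.803 for covered share, 0.907 for density and 0.912 for width. They departed from 1 by less than the SD over autosomes, which for covered share and density is widened by chromosome 19, far above the others. These ratios came to 0.942, 0.973 and 0.992 when only the 75% of HMRs highest in level were kept. Without the 25% highest in level they were 0.722, 0.818 and 0.888. The median level was higher on X than on any autosome in both species, at 0.164 in human sperm (autosomal median 0.117) and 0.104 in chimpanzee sperm (autosomal median 0.0766).

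**Figure D2:**
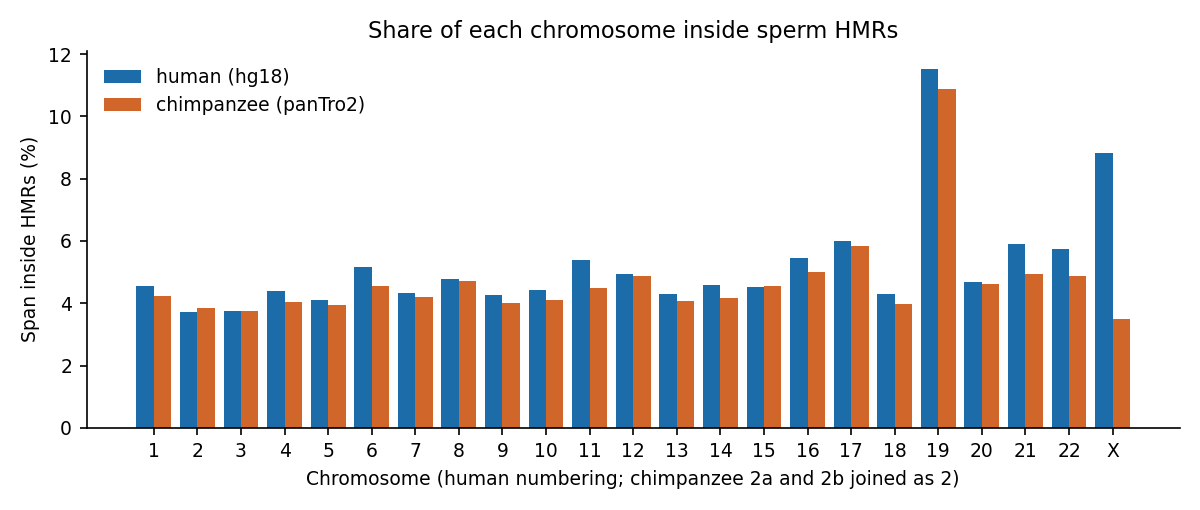
Percentage of each chromosome's span inside HMRs (bars, vertical axis) for human and chimpanzee sperm, by chromosome in human numbering. Human X reaches 8.83% and chimpanzee X 3.49%, while chromosome 19 is the highest bar in both species, at 11.5% and 10.9%.

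The human excess on X lay mostly around the centromere and on the near part of the long arm, and long regions made up much of it. Human X held 896 HMRs of at least 4 kb and chimpanzee X 212, a ratio of 4.23, whereas the highest autosomal ratio was 1.18. The human long regions on X were also more methylated, with a median level of 0.184 against 0.0357 for autosomal regions of that size and 0.0292 on chimpanzee X. At least 10% of the sequence was inside HMRs in 31 of 151 windows of 1 Mb on human X that held an HMR, and in 1 of 154 on chimpanzee X. The longest stretches of such windows on human X lay at 54 to 59 Mb, 61 to 68 Mb and 74 to 83 Mb, where HMRs covered 29.6%, 36.6% and 25.1% on average. Of the 31 such human windows, 29 had a median level above 0.15. Between 50739832 and 87184421 bp on human X, HMRs covered 22.4% at 62.0 regions per Mb, against 4.53% and 23.5 per Mb between 51045960 and 87411457 bp on chimpanzee X, the stretch bounded by the same matched chains. On the rest of X the shares were 4.92% in human and 3.20% in chimpanzee sperm, a ratio of 1.54. The stretch held 76.1% of the human excess of covered length on X. Those bounds were chosen after the windows had been seen. When the 25% of HMRs highest in level were left out of both lists, the human to chimpanzee ratio of covered length on X was 1.88, against at most 1.13 on autosomes. Each list was cut at its own upper quartile, 0.189 in human and 0.155 in chimpanzee sperm. Of the X regions of at least 4 kb, 598 of 896 human and 33 of 212 chimpanzee ones had levels above 0.15. A cut at the same level in both lists was not made, so 1.88 does not show what such a cut would leave. Without that 25%, the covered share of human X relative to the human autosomal median was 1.28, in place of 1.93. It departed from 1 by less than the SD over autosomes of 0.368, which includes chromosome 19.

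**Figure D3:**
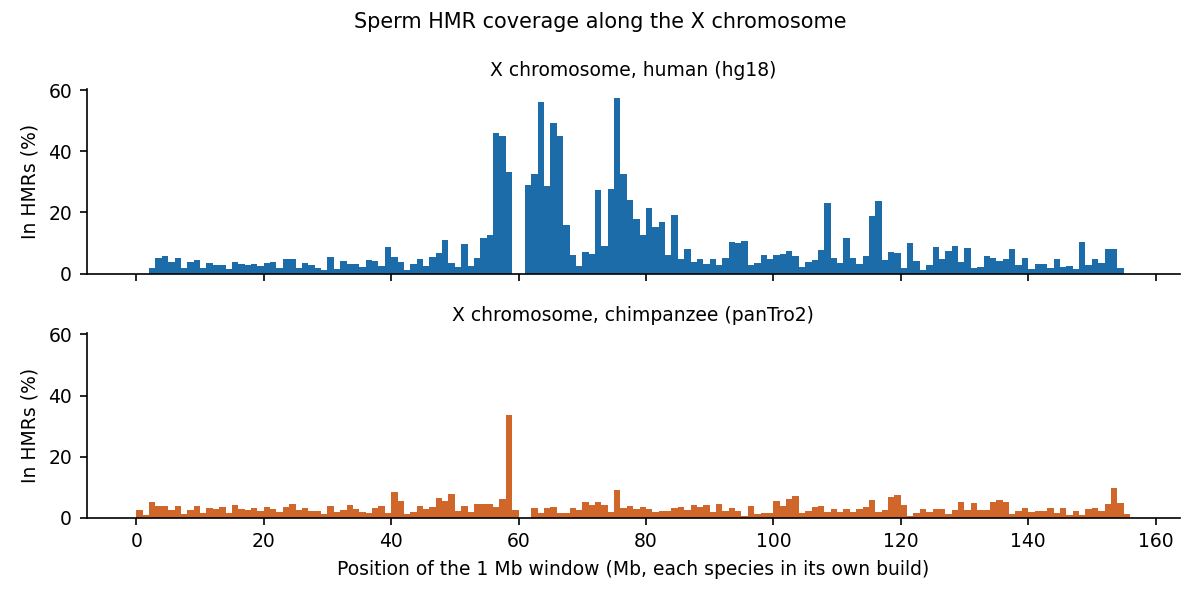
Percentage of each 1 Mb window of X inside HMRs (bars, vertical axis) along X in Mb, for human (hg18) and chimpanzee sperm (panTro2), each in its own coordinates. Human windows at 54 to 59 Mb, 61 to 68 Mb and 74 to 83 Mb all hold at least 10%, with a highest value of 57.5% at 75 Mb, windows farther out reach up to 23.8% at 116 Mb, and chimpanzee X has 1 window of at least 10%, at 58 to 59 Mb.

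Chromosomes rich in HMRs in human sperm were mostly also rich in them in chimpanzee sperm. X was an exception, with 35.3 per Mb and 1 autosome above it in human sperm, and 22.2 per Mb and 18 autosomes above it in chimpanzee sperm. Chromosome 19, the most gene-dense human chromosome, led in both species with 54.1 HMRs per Mb in human and 52.6 in chimpanzee sperm. The lowest densities were 23.6 per Mb on human chromosome 2 and 21.5 per Mb on chimpanzee chromosome 3. Over the 23 chromosomes, density was correlated between the species with Pearson's r = 0.93 (two-sided permutation p = 0.00028, adjusted p = 0.00042) and Spearman's rho = 0.79 (p = 2e-05, adjusted p = 3e-05). Without chromosomes 19 and X, the farthest from the median in human sperm, r was 0.90 (p = 1e-05, the smallest that these permutations can give). For covered share r was 0.78 (p = 0.00862, adjusted p = 0.00862) and rho 0.72 (p = 0.00016, adjusted p = 0.00016), with r = 0.89 without chromosomes 19 and X (p = 1e-05). For median width r was 0.78 (p = 8e-05, adjusted p = 0.00024) and rho 0.77 (p = 2e-05, adjusted p = 3e-05), with r = 0.60 without chromosomes 19 and 22 (p = 0.00597). These 3 relations were adjusted together by the Benjamini-Hochberg method, and chromosomes are not biological replicates.

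HMRs lay closer together than random placement of the same regions gave. In human sperm 18.4% of the gaps between neighbouring HMRs were under 5 kb, against a mean of 13.9% over 1000 random placements on the same chromosomes, a ratio of 1.32. In chimpanzee sperm the shares were 16.6% and 12.3%, a ratio of 1.35. Under 1 kb the ratios were 1.53 in human and 1.17 in chimpanzee sperm. With HMRs under 500 bp apart merged, which removes the shortest gaps, the ratios under 5 kb were 1.17 in human and 1.24 in chimpanzee sperm. The random placements could still give gaps under 500 bp, so lower ratios follow from the merging and do not measure weaker clustering. No random placement reached the observed share of gaps under 5 kb, and p was 0.001 in each species, the smallest that 1000 placements can give. The test concerns arrangement within a list and not a difference between species.

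The HMRs in the 5 densest 1 Mb windows had levels above the list median in human sperm, while 3 of the 5 windows in chimpanzee sperm held HMRs with levels below the median of their list. In human sperm the 5 densest were chromosome 7 at 61 to 62 Mb with 119 HMRs, chromosome 8 at 43 to 44 Mb with 113, and X at 57 to 58 Mb, 75 to 76 Mb and 56 to 57 Mb with 110, 109 and 107, against a median window of 25. In these human windows the median level of the regions was between 0.186 and 0.232. In chimpanzee sperm they were chromosome 16 at 44 to 45 Mb with 108 HMRs, chromosome 8 at 8 to 9 Mb with 104, chromosome 19 at 54 to 55 Mb with 101, chromosome 6 at 28 to 29 Mb with 97 and chromosome 19 at 1 to 2 Mb with 91, against a median window of 22. The chimpanzee windows on chromosomes 19 and 6 had median levels of 0.0422, 0.0450 and 0.0385, while those on chromosomes 16 and 8 stood at 0.271 and 0.210.

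The 5 longest HMRs of each list spanned over 50 kb, and 9 of the 10 had levels above the median of their list. In human sperm they lay on chromosome 4 at 9797615 to 9962624 (165.0 kb, level 0.198), chromosome 12 at 34331509 to 34431543 (100035 bp, level 0.10), chromosome 4 at 48786654 to 48855350 (68.7 kb, level 0.161), chromosome 6 at 63596487 to 63652641 (56.2 kb, level 0.157) and chromosome 1 at 142079824 to 142134276 (54.5 kb, level 0.154). In chimpanzee sperm they lay on chromosome 8 at 43979432 to 44068206 (88.8 kb, level 0.154), chromosome 15 at 22590313 to 22662210 (71.9 kb, level 0.141), chromosome 5 at 65965589 to 66031520 (65.9 kb, level 0.136), chromosome 16 at 44371920 to 44437758 (65.8 kb, level 0.148) and chromosome 21 at 46358370 to 46418735 (60.4 kb, level 0.212). Genes at these places are not given here because the gene table at hand is of another build.

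Most HMRs were given a partner in the other species' list, though the shares in both species depended on the matching rule and the regions kept. Matching by order and spacing alone paired 48540 HMRs, which was 61.9% of the human list (Wilson 95% interval 61.6 to 62.2%) and 69.7% of the chimpanzee list (69.4 to 70.0%), intervals that cover counting error only. On autosomes the shares were 64.5% and 71.2%, and on X they were 25.6% and 39.8%. The matched chains enclosed 88.8% of human HMRs, 92.3% on autosomes and 40.1% on X. Inside the chains X was closer to the autosomes, with 63.8% of human HMRs paired against 69.9%. When distances were aligned on neighbouring pairs, 72.8% of human HMRs inside chains overlapped a chimpanzee HMR, against 18.4% after the map was moved by 50 kb, a contrast that pairing by distance itself favours. The share paired was 41.0% of human and 46.1% of chimpanzee HMRs when only the 75% of HMRs highest in level were kept in each list. It was 48.5% of human and 54.7% of chimpanzee HMRs when partners had to overlap by at least 50% of the shorter region.

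The order of HMRs followed some of the known large rearrangements between the genomes and not others. The 73 chains spanned between 0.473 Mb on X and 110.0 Mb on chromosome 2, with up to 1980 pairs in a chain on chromosome 1. Stretches such as 38.7 to 70.1 Mb on chromosome 9 and much of X had no chain. Human chromosome 2, known to be a fusion of the ancestors of chimpanzee 2a and 2b, was matched to 2a up to 107.5 Mb and to 2b from 117.2 Mb. In 13 chains the order was reversed, with 4039 pairs on 8 chromosomes. The reversed stretch on chromosome 12 ran from 21294183 to 66683995 bp with 933 pairs. On chromosome 5 reversed chains of 519, 294 and 369 pairs lay between 18.7 and 96.0 Mb, on chromosome 17 chains of 146 and 603 pairs lay between 7.88 and 45.0 Mb, on chromosome 4 a chain of 556 pairs ran from 54.2 to 84.8 Mb, and on chromosome 18 a chain of 261 pairs ran from 0.148 to 14.1 Mb. The other reversed chains lay on chromosome 1 (179 and 32 pairs), chromosome 4 (51 pairs), chromosome 7 (46 pairs) and X (50 pairs), and the score of the last, 38.8, was close to the threshold of 34.5. Pericentric inversions between the karyotypes are known on chromosomes 1, 4, 5, 9, 12, 15, 16, 17 and 18, and no reversed pairs were found on chromosomes 9, 15 and 16.

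**Figure D4:**
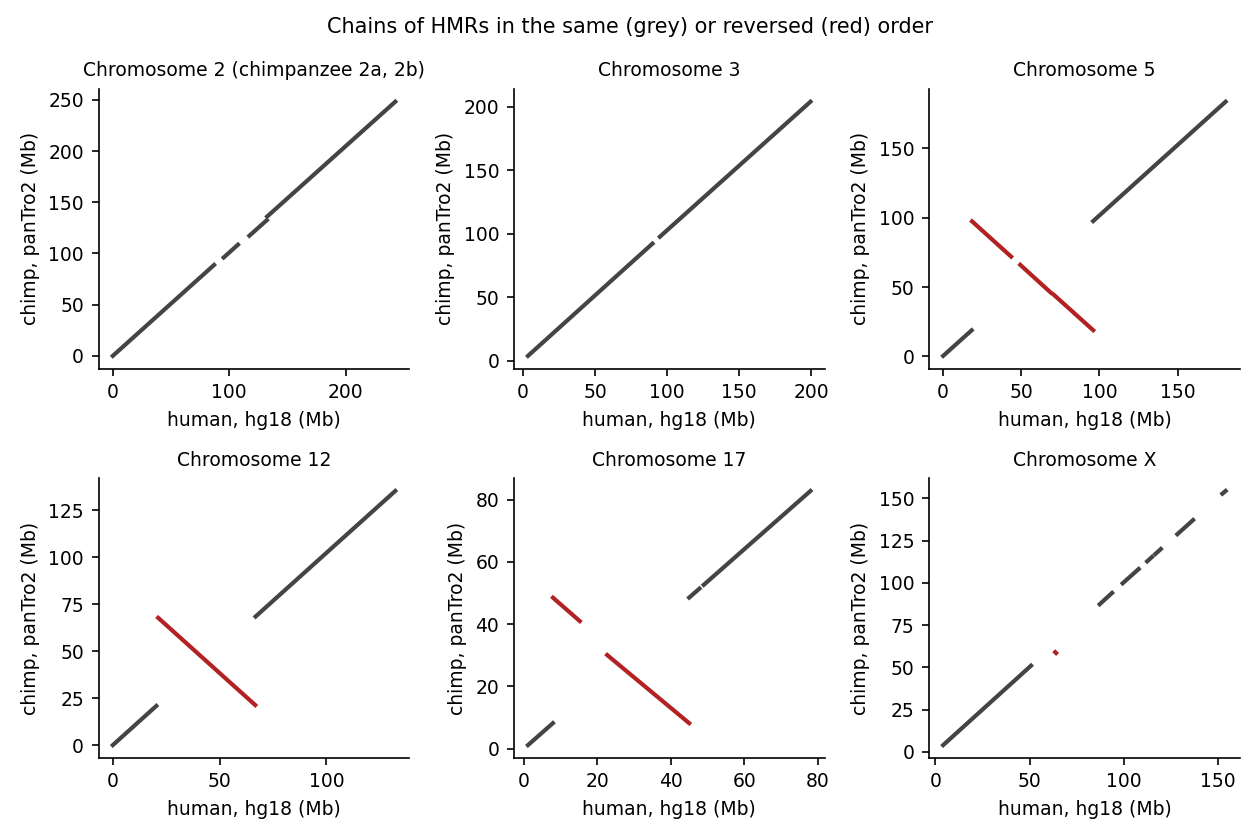
Position of matched HMRs on 6 chromosomes, human hg18 in Mb on the horizontal axis and chimpanzee panTro2 in Mb on the vertical axis, 1 line per chain in the same order (grey) or reversed order (red). Chromosomes 5, 12 and 17 show reversed stretches, chromosome 2 is covered by chimpanzee 2a and 2b placed end to end, and X lacks chains over most of the stretch from 50.7 to 87.2 Mb, apart from a short reversed one at 64.0 Mb.

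Paired HMRs had similar widths, with a small shift toward the chimpanzee member that depended on the regions kept. The median log2 ratio of chimpanzee to human width was 0.05 (quartiles -0.28 and 0.39), a fold of 1.04, and its median was above 0 on 23 of 23 chromosomes, from 0.00 on chromosome 19 to 0.11 on chromosome 15. With only the 75% of HMRs highest in level it was 0.014, less than its SD over chromosomes of 0.023. The members were within 2-fold of each other in 80.4% of pairs. The human member was more than 2-fold wider in 10.5% of pairs (interval 10.2 to 10.8%) and the chimpanzee member in 9.16% (8.91 to 9.42%). On X those shares were 20.9% and 12.5%. Across pairs, Spearman's rho was 0.72 for width and 0.71 for level, and 0.55 for width on X, with pairs not being independent replicates. The level was lower in the chimpanzee member in 64.8% of pairs. The order of the shares over 2-fold turned to 12.1% wider in human and 13.8% in chimpanzee in that list.

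The pairs with the greatest width ratios set a very long region in one species against a short one in the other. Among pairs with both members of at least 500 bp, the human member was widest relative to its partner for the 165.0 kb region of chromosome 4, whose chimpanzee partner spanned 2.44 kb (67.7-fold). It was followed by chromosome 11 at 3430203 to 3461425 (60.4-fold), chromosome 4 at 4006573 to 4039989 (52.8-fold) and 4050860 to 4092196 (36.5-fold), and chromosome 2 at 119315193 to 119333848 (35.6-fold). The last differed from the others in level, at 0.0167 in human and 0.00292 in chimpanzee sperm. In the other direction the 88.8 kb chimpanzee region of chromosome 8 was paired with a human HMR of 596 bp (149-fold), followed by chimpanzee chromosome 15 at 22590313 to 22662210 (87.3-fold), chromosome 5 at 65965589 to 66031520 (55.5-fold) and 65939418 to 65965354 (44.6-fold), and chromosome 12 at 52406219 to 52449389 (36.1-fold). The 2 chimpanzee regions on chromosome 5 lay under 500 bp apart, so they need not be separate cases. The shorter member lay wholly inside the longer one in all 10 pairs, once distances were aligned on neighbouring pairs. The matching accepts agreement of the start, the end or the middle of the regions. For widths so unequal that makes such containment likely, so it is not separate evidence of a shared place.

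HMRs without a partner were narrower and more methylated than paired ones in both species. Inside the chains, the 21073 unpaired human HMRs had a median width of 718 bp and a median level of 0.173, against 1492 bp and 0.0917 for paired ones. The 16566 unpaired chimpanzee HMRs had a median width of 752 bp and a median level of 0.130, against 1482 bp and 0.0616. The share paired increased with width, from 32.2% (30.8 to 33.6%) of human regions narrower than 250 bp to 89.7% (88.8 to 90.5%) of those of at least 4 kb, and from 39.3% (37.7 to 40.9%) to 91.9% (91.2 to 92.6%) in chimpanzee sperm. In narrow regions the relation with level could be the opposite. Below 250 bp, 27.2% of human HMRs were paired in the lowest and 33.8% in the highest of 3 equal classes of level, with 24.0% and 45.3% in chimpanzee sperm. Between 250 and 500 bp the shares were 35.0% and 53.6% in chimpanzee sperm, and 49.2% and 39.4% in human sperm. Over 2 kb, 2314 human and 1962 chimpanzee HMRs inside the chains were unpaired. The median width of unpaired over paired chimpanzee HMRs was 0.507, and 0.784 when only the 75% of HMRs highest in level were kept.

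**Figure D5:**
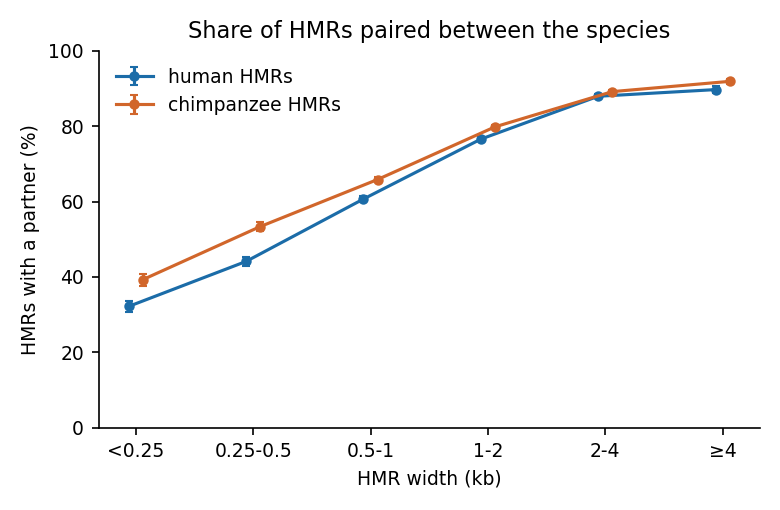
Percentage of HMRs inside matched chains that had a partner in the other species (vertical axis) by width class in kb (horizontal axis), with Wilson 95% intervals as error bars. The share climbs from 32.2% to 89.7% in human and from 39.3% to 91.9% in chimpanzee sperm.

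The longest unpaired HMRs inside chains were between 16.6 and 36.2 kb wide. Unpaired here does not mean that the other species lacked an HMR there, since 3 of the 5 human and 5 of the 5 chimpanzee regions overlapped one after alignment on neighbouring pairs, and the overlap that chance gives regions of this width was not computed. In human sperm they were chromosome 12 at 36275358 to 36298751 (23.4 kb) and 113029272 to 113052584 (23.3 kb), chromosome 4 at 9963256 to 9983028 (19.8 kb), chromosome 21 at 14177188 to 14193852 (16.7 kb) and chromosome 8 at 6983414 to 6999987 (16.6 kb), with levels from 0.214 to 0.271. In chimpanzee sperm they were chromosome 9 at 85365266 to 85401496 (36.2 kb), chromosome 12 at 54466855 to 54493046 (26.2 kb) and 52150336 to 52172063 (21.7 kb), chromosome 6 at 29242931 to 29267498 (24.6 kb) and chromosome 7 at 59267466 to 59285980 (18.5 kb). The levels of these chimpanzee regions were 0.207 on chromosome 9, 0.0320 and 0.148 on chromosome 12, 0.0826 on chromosome 6 and 0.163 on chromosome 7. The unpaired human region on chromosome 4 began under 2 kb after the paired 165.0 kb HMR, so it need not be a separate case.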

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

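The test of a human list that is richer on every chromosome and the test of missed partners were chosen after their results had been seen, as were the count of marginal calls over all 6 width classes and the lists without the 25% of HMRs highest in level. Chromosome X was flagged because it lay above the autosomal median in human and below it in chimpanzee sperm, a difference that was not tested, since each species has 1 list. Relative to the autosomal median, HMR density on X was 1.31 in human and 0.907 in chimpanzee sperm, median width was 1.31 and 0.912, and the covered share was 1.93 and 0.803. The human values departed from 1 by more than the SD over autosomes and the chimpanzee values by less. Chromosome 19 widens that SD, with 11.5% covered in human and 10.9% in chimpanzee sperm. Every other autosome was at or below 5.99% in human and 5.82% in chimpanzee sperm. A value within the SD is therefore not shown to be ordinary, and chimpanzee X was below each of the 22 autosomes in covered share. With HMRs under 2 kb apart merged, human density on X was 1.15 and departed from 1 by less than that SD. Human width and covered share, at 1.27 and 1.997, still departed by more. Without the 25% of HMRs highest in level the human values were 1.04, 1.15 and 1.28, each within the SD over autosomes of 1, and the chimpanzee values were 0.818, 0.888 and 0.722. With only the 75% highest in level the human values were 1.52, 1.48 and 2.74 and the chimpanzee values 0.973, 0.992 and 0.942.

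A human list that is richer by a like factor on every chromosome was argued against. The human to chimpanzee ratio of covered length was 2.47 on X and at most 1.25 on autosomes. A depth or caller that admits more partly methylated regions in human sperm could act most on X, which this test cannot exclude. The median level on X was above that of every autosome in both species, at 0.164 in human and 0.104 in chimpanzee sperm. Merging neighbours under 2 kb apart left the ratio of covered length at 2.50, with at most 1.27 on autosomes. That ratio cannot decide whether chimpanzee X regions were split into pieces, since splitting removes only the gaps from covered length. After merging, the ratio of numbers was 1.4 on X and at most 1.19 on autosomes. The ratio of median widths was 1.32 on X and at most 1.05 on autosomes. Splitting into pieces under 2 kb apart therefore does not account for the whole difference in width. Short marginal calls could not account for it either, since among regions of at least 4 kb the ratio of numbers was 4.23 on X and at most 1.18 on autosomes. Open technical explanations are the read depth on X, mapping to repeats and segments near the centromere, and the assembly of chimpanzee X, none of which the lists can decide. A species difference in sperm methylation of X may also contribute and stays open as an untested hypothesis.

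HMRs without a partner were narrower and more methylated in both species. Whether the chains missed partners at the same place cannot be told apart from true absence, because an HMR with a counterpart at the expected place is already taken into the chain. For that reason the bound set for this test was wrong, and the 10.2% (9.76 to 10.6%) of unpaired human HMRs that overlapped a chimpanzee HMR after the offset was removed lay below the 15.7% found with the map moved by 50 kb. Marginal calls, which one list would hold and the other miss by chance, could account for part of the pattern, since the share paired was lower at the highest than at the lowest level in 5 of 6 human and 4 of 6 chimpanzee width classes. They stay open, as does a true species difference, because the order was the opposite in the other 3 classes, with 27.2% (23.8 to 31.0%) paired at the lowest and 33.8% (32.1 to 35.5%) at the highest level below 250 bp in human sperm, 24.0% and 45.3% below 250 bp in chimpanzee sperm, and 35.0% (31.5 to 38.7%) and 53.6% (52.1 to 55.1%) between 250 and 500 bp in chimpanzee sperm.

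Chains of HMRs in the same order and spacing could arise by chance between dense maps. The second set of searches between non-homologous chromosomes gave 0.105% as many pairs as the homologous ones, which argues against chance for the bulk of the pairs. That set does not bound the error of single pairs inside a true chain, where a neighbouring HMR can be taken in place of the homologous one, and 87.5% of pairs overlapped after the offset was removed.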

How the results depend on the processing

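Lists without the 25% of HMRs highest in level, merging under 2 kb and pairing by any overlap were chosen after the data had been seen. Of 80 values under alternatives for 19 results, 52 moved by less than the spread over chromosomes or the counting interval or kept their side of the test, 26 moved further and 2 reversed. For covered length that spread included X and was 0.302, wider than the distance of the ratio of 1.12 from 1. The ratio of 1.06 on autosomes only thus counted among the 52, which are not a measure of stability for that result. Both reversed values were of the ratio of median widths, human over chimpanzee. It was 1.01 with merging under 500 bp and 1.01 with HMRs of at least 1 kb only, and the cause was not tested. Each share was judged alone and could not count as reversed. With the upper 75% in level, pairs over 2-fold wider turned to 12.1% in human and 13.8% in chimpanzee sperm, and both count among the 26. Ratios of number and covered length kept their direction, as did the correlation of densities and the clustering, under each alternative run for them. The clustering ratios under 5 kb were smaller with merging under 500 bp, at 1.17 in human and 1.24 in chimpanzee sperm. A decrease follows from the merging itself, since the random placements could still give gaps under 500 bp.

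Restricting to the upper 75% in level moved the X to autosome ratio in human sperm to 2.74 for covered share and 1.48 for width, and the paired share to 41.0% of human and 46.1% of chimpanzee HMRs. It moved the median log2 width ratio to 0.014, pairs over 2-fold wider to 12.1% in human and 13.8% in chimpanzee sperm, and the unpaired to paired width ratio to 0.711 in human and 0.784 in chimpanzee sperm. Without the 25% highest in level, X to autosome ratios in human sperm were 1.28 for covered share, 1.04 for density and 1.15 for width, paired shares were 64.1% and 72.2%, and pairs over 2-fold wider were 7.49% in human and 6.26% in chimpanzee sperm. Paired shares, human then chimpanzee, were 57.6% and 64.9% with the tolerance halved, 63.6% and 71.7% with it doubled, 48.5% and 54.7% with an overlap of at least 50%, and 64.6% and 73.9% by any overlap. Requiring that overlap of 50% gave 9.94% of pairs over 2-fold wider in human and 8.16% in chimpanzee sperm. Causes of these shifts were not tested. No paired analysis was possible because each species has 1 list and donor numbers do not pair donors across species. Leaving out a donor and the gene annotation alternatives were not run, and the unknown depth limits every comparison of levels and numbers between the species.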

Other observations

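The test of whether the excess on X lies in a few windows was set before its result was seen, while the peak of widths and the ends of X were looked at after the data had been seen. Widths had a narrow peak in both species. In classes of 10 bp between 180 and 419 bp, the class from 270 to 279 bp held 591 human HMRs, 2.06 times the median of 287.5 over the 20 classes outside 250 to 289 bp, whose highest held 353. In chimpanzee sperm the same class was the fullest, with 377 HMRs against a median of 262.5 and a highest other class of 314, a ratio of 1.44. HMRs of 250 to 289 bp had a median level of 0.188 in human and 0.166 in chimpanzee sperm, and 38.7% (36.3 to 41.1%) and 48.7% (45.9 to 51.6%) of those inside chains were paired. The paired shares were 37.1% (34.3 to 39.97%) and 44.9% (41.8 to 48.0%) at the narrower neighbouring widths of 210 to 249 bp, and 42.3% (39.3 to 45.4%) and 48.1% (44.9 to 51.4%) at 290 to 329 bp.

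On X the first human HMR started at 2729505 bp and the first chimpanzee HMR at 44038 bp, each in its own build.

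The human excess on X might lie in a few windows of very high coverage. It did so only in part, because the human to chimpanzee ratio of the median covered length per 1 Mb window was 1.67 on X and at most 1.14 on autosomes, and the covered share outside the stretch between chains was still 1.54 times higher in human sperm. Without the 25% of HMRs highest in level, the ratio of covered length on X was 1.88 against at most 1.13 on autosomes. That cut lay at 0.189 in human and 0.155 in chimpanzee sperm, so the ratio does not compare the species at a like level.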
